A study of Malus domestica with 8 samples.

How the data were processed

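Leaf messenger RNA was measured by sequencing in 8 libraries of the apple cultivar 'Gala' (Malus domestica), 2 from non-transformed plants (wt) and 2 from each of 3 CRISPR/Cas9 lines, mdagg-2, mdagg-3 and mdagg-4, in which MdAGG was the target of the knock-out. Per the labels' protocols, rooted in vitro plants were grown for 8 weeks in a greenhouse at 22 °C and 80% relative humidity, sprayed to runoff with acibenzolar-S-methyl (ASM) at 0.2 g/l, and sampled 3 days later. Every library came from a treated plant lot, so no comparison here measures the response to ASM. RNA was extracted with a plant spin-column kit and libraries were made with a stranded Illumina mRNA kit, per the labels' protocols. The series' design text describes the 2 libraries of a group as leaf bulks of 2 independent experiments, and they were treated as biological replicates.

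For each library the authors deposited a table in the column layout of Salmon, a program that assigns reads to annotated transcripts. Per the file headers it holds for 52311 features the transcript length, the effective length, the TPM and the estimated count of reads. Salmon and DESeq2 are named, without versions, in the submitters' processing notes, and the genome build and annotation are not given in the sources used here. The estimated count is an expected count that is not normalized and need not be whole, per the file headers and the values, of which 67.9% were exactly whole, values of 0 included. The TPM values, scaled to the same sum in each library by the authors' Salmon run, were read and not tested. The authors also deposited a table of each line against wt, with 1 whole-number count column per library, log2 fold changes, p-values and adjusted p-values, per the file headers. The count columns of 8 libraries in that table equalled the rounded estimated counts for all features. The table repeats the control columns for each line, and the 4 repeats were not used. The log2 fold changes and p-values of the authors' deposited table were copied as they stand and are named as such where they are printed.

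Estimated counts were rounded to whole numbers. Features were kept by edgeR's filterByExpr, which left 32373 of 52311, and libraries were scaled with TMM factors. Differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) in 1 fit of all 8 libraries with a mean per group and 4 residual degrees of freedom, so that the groups of 2 shared their estimate of the spread. The contrasts were each line against wt, the mean of the 3 lines against wt, and an F test for any difference among the 3 lines. Benjamini-Hochberg adjustment was applied over the 32373 features, with a threshold of 0.05 on the adjusted p. A standard error of a log2 fold change was taken as its size divided by the square root of F. Normalised read counts are CPM after TMM scaling, and log2 CPM used a prior count of 2. The fit was tested on simulated data made from the libraries' own means, spread and sizes. For the mean of the lines, with 200 features changed among 31979 tested, it recovered 10% of 50 features changed 2-fold, 74% at 4-fold, 92% at 8-fold and 96% at 16-fold, with 17 false calls. For mdagg-2 alone, among 31978 features, the shares were 2%, 60%, 80% and 92%, with 9 false calls. The simulation drew each feature independently and held no shift common to many features, so these shares may not hold for the real libraries.

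Feature identifiers were used exactly as deposited. None of the 52311 identifiers (0) matched the reference table of gene names, which follows assembly GDT2T_hap1, and the deposited files do not pair identifiers with names. The 32 gene lists fixed before the data were examined, among them markers of other leaf cell types and of stress, therefore had 0 matched members and were not tested. The rule for named genes asked for the MdAGG family, the largest changes past the threshold in each comparison, and members of the lists, each with a description in the files. It named no gene, and 4 identifiers are printed that were chosen after their values were seen. Transcripts of MdAGG are not analysed here by name, so the knock-out labels were not checked against their target.

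After the data were examined, log2 differences from wt were also scanned along the identifiers. In the apple gene nomenclature the 2-digit field after the letters MD stands for the chromosome in fields 01 to 17, and the following number rises along it, while field 00 holds features not placed on a chromosome, whose order carries no position. The files give no coordinates, and order here means identifier order only. The scan took 17534 features with a mean log2 CPM above 3, subtracted the median difference of each line, limited differences to 1.5 either way, and searched each of 18 fields for the run of at least 20 consecutive features with the largest sum divided by the square root of its length. Runs were kept when they exceeded the largest value in 100 shuffled orders, and the features on either side of a kept run were then searched in the same way. Medians carry 95% bootstrap intervals over features (1000 draws), which measure the spread between features and not between plants. On shuffled mdagg-2 differences (17534 features), the scan found an inserted run of 200 features raised by 0.4 and one of 50 features lowered by 1, covering 99.5% and 100% of them, with 0 false runs. The inserted runs were placed in the fields of the 2 runs described in the results, with similar lengths and sizes. Smaller or shorter runs were not tried, and the check used fewer shuffled orders than the scan. The scan and the plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

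Library totals lay between 28591909 and 36995911 estimated reads, at which 3 reads correspond to 0.0811 to 0.105 CPM before TMM scaling. Alternatives set before the data were examined were DESeq2 size factors in place of TMM, no low-count filter, DESeq2 (1.42.0) in place of edgeR, the replicate number as a block, the effective lengths of each library as an offset, each library left out in turn, the 6 knock-out libraries as one group, and fits of only the 4 libraries of a line and wt. Fits with limma-voom (limma 3.58.1), without 2 libraries that stood apart, without the features of the 2 runs described in the results, and with DESeq2 on the 4 libraries of each line were added after the data were examined. The DESeq2 fits of the deposited counts were made without the low-count filter.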

Results

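The data comprised 8 leaf libraries of the apple cultivar 'Gala' in 4 groups of 2, the non-transformed control (wt) and the CRISPR/Cas9 lines mdagg-2, mdagg-3 and mdagg-4, all collected 3 days after a spray with acibenzolar-S-methyl, a synthetic inducer of plant defence that acts in place of salicylic acid. MdAGG, the target of the knock-out in these lines, stands for apple agglutinin, a carbohydrate-binding protein. Total estimated reads were 34553413 and 36995911 in the wt libraries, 31807423 and 28591909 in mdagg-2, 32350520 and 36381307 in mdagg-3, and 34923043 and 36061600 in mdagg-4. The deposited files do not pair feature identifiers with gene names, so transcripts of MdAGG are not analysed here by name and features are given by identifier.

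Libraries of the same group were no closer to each other than to libraries of other groups. The correlation of log2 CPM across 32373 features, which are not independent replicates, had a median of 0.969 over the 4 pairs of libraries within a group and 0.968 over the 24 pairs from different groups. Within groups it ranged from 0.943 to 0.976, and between groups from 0.907 to 0.981. The first principal component held 46.3% of the variance. On the first component the mdagg-2 libraries scored -100.2 and 41.9 and the mdagg-4 libraries 15.5 and 93.1, while those of mdagg-3 scored -43.3 and -40.5 and those of wt -1.44 and 35.0. Replicate 2 scored above replicate 1 in all 4 groups. The libraries mdagg-2 replicate 1 and mdagg-4 replicate 2 thus stood at the ends of the component. As a check for a library deposited more than once, the counts of the 2 libraries of a group were compared, and no pair agreed within sampling noise (chi-square per feature 47.3 to 89.5).

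**Figure D1:**
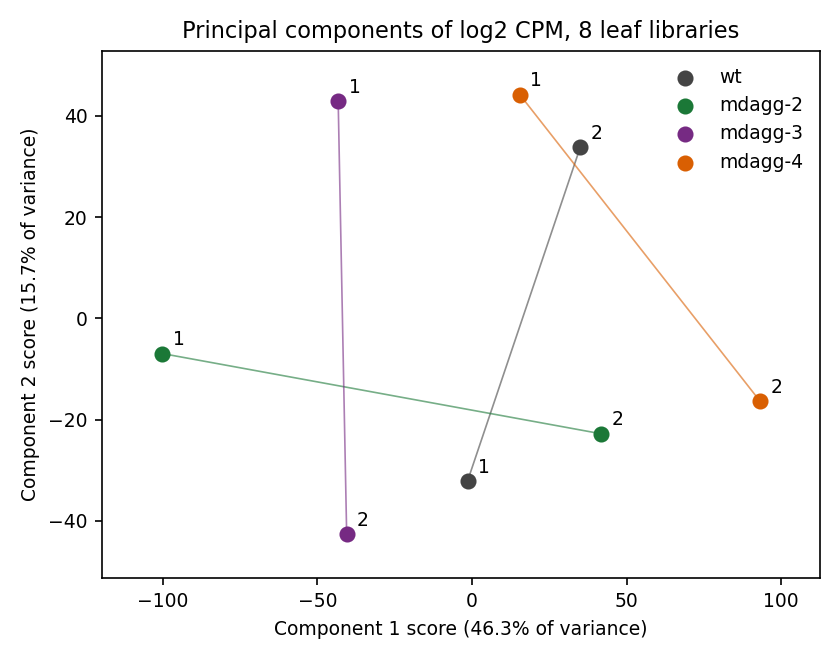
Scores of the 8 libraries on the first component (x axis, 46.3% of the variance) and the second (y axis) of log2 CPM; colours mark groups, numbers the replicate, and lines join the 2 libraries of a group. The mdagg-2 libraries lie at -100.2 and 41.9 on the first component and the mdagg-4 libraries at 15.5 and 93.1.

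The comparison of the 3 lines with wt asks which leaf transcripts differ between the knock-out lines and non-transformed plants. The libraries include no transformed plants without the knock-out. Loss of MdAGG is therefore not separated from the effects of transformation and regeneration. For the mean of the lines, 0 features were higher and 0 were lower than wt at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 929 of 32373 features (2.87%, where chance gives 5%), and the smallest adjusted p was 0.133. DESeq2 on the same 8 libraries gave 53 higher and 19 lower. That fit used no low-count filter and gave an adjusted p to 39707 features, so test and feature set both differ. Without the filter edgeR gave 2 higher and 4 lower. The feature with the smallest p was MD13G1190500, at 0.386 ± 0.0319 CPM in wt (SD, n = 2), 2.08 ± 0.407 in mdagg-2, 2.01 ± 0.209 in mdagg-3 and 11.1 ± 1.17 in mdagg-4, a mean log2 difference of 3.21 ± 0.28 (SE). The next was MD05G1005300, at 2.53 ± 0.277 CPM in wt (SD, n = 2) and 0.244 ± 0.0697 in the 6 knock-out libraries (SD, n = 6). Its log2 difference was -3.37 ± 0.33 (SE, edgeR adjusted p = 0.15), and all 6 knock-out libraries, with 6 to 11 reads, lay below both wt libraries, with 80 and 105 reads. That difference passed the threshold without the low-count filter (edgeR adjusted p = 0.017), with the 6 knock-out libraries as one group (0.0306) and in DESeq2 (3.25e-07). The adjusted p over its 17 alternatives ranged from 3.25e-07 to 1. Of the 32373 features, 935 were higher in all 6 knock-out libraries than in both wt libraries (2.89%) and 498 were lower in all 6 (1.54%), where chance gives 3.57% each. The mean differed by at least 2-fold in 250 and 83 of these.

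Each line was next set against wt. In mdagg-2, 1 feature was higher and 0 were lower in edgeR's test, with 1181 features at an unadjusted p under 0.05. It was MD17G1123100, at 19.7 ± 0.813 CPM in mdagg-2 (SD, n = 2) and 0.112 ± 0.0481 in wt (SD, n = 2), a log2 difference of 7.43 ± 0.36 (SE, edgeR adjusted p = 0.00163). The mdagg-2 libraries held 588 and 565 reads of it and the other 6 libraries 3 to 5 reads each. Without wt replicate 2 its edgeR adjusted p was 0.057, with a log2 difference of 7.04, and over its 18 alternatives the adjusted p ranged from 4.21e-29 in a DESeq2 fit to 0.143 in edgeR with only the 4 libraries of mdagg-2 and wt. In mdagg-3, 0 features were higher and 0 were lower, with 1014 at an unadjusted p under 0.05 and a smallest edgeR adjusted p of 0.9. In mdagg-4, 1 feature was higher and 0 were lower, with 953 at an unadjusted p under 0.05. It was MD13G1190500, with 353 and 478 reads in mdagg-4 and 14 in each wt library, a log2 difference of 4.83 ± 0.31 (SE, edgeR adjusted p = 0.0158). Leaving out either wt library, either mdagg-3 library or either mdagg-4 library ended that call, with edgeR adjusted p values of 0.0814 to 0.564 and log2 differences of 4.72 to 4.93. Over its 18 alternatives the adjusted p ranged from 5.72e-25 in a DESeq2 fit to 0.564. Leaving out either mdagg-2 library gave 1 lower feature in mdagg-4. DESeq2 on all 8 libraries gave 28 higher and 9 lower in mdagg-2, 31 and 9 in mdagg-3, and 50 and 44 in mdagg-4.

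**Figure D2:**
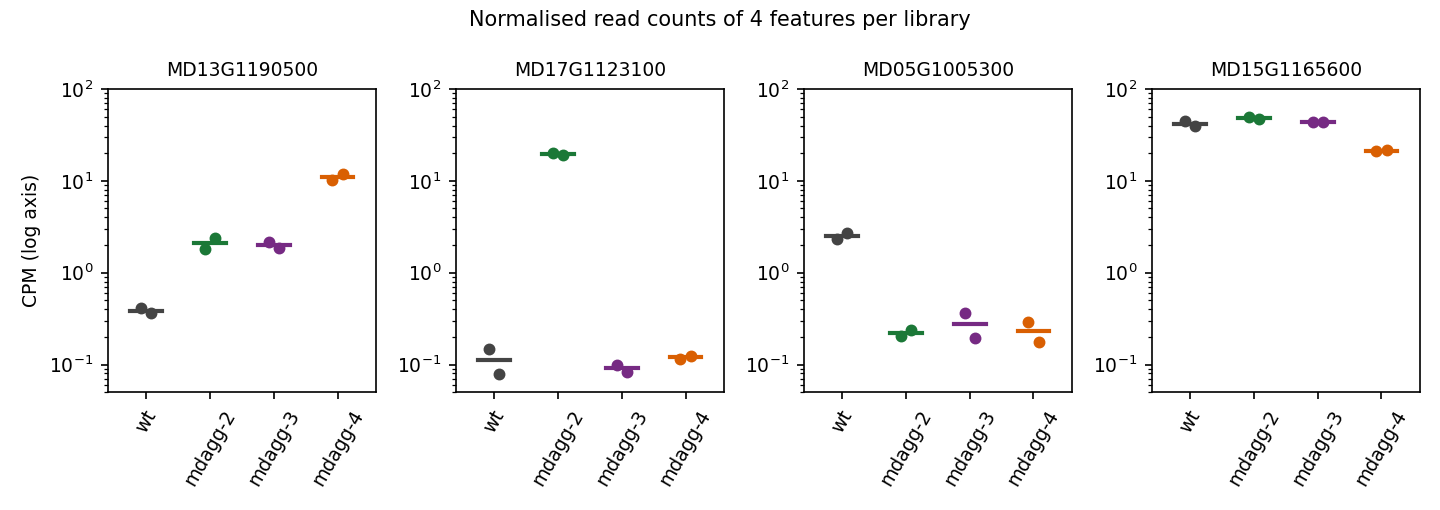
Normalised read counts (CPM, log axis) of 4 features named in the text in each library; points are libraries, horizontal bars the mean of the 2 libraries of a group. MD17G1123100 stands at 19.7 CPM in mdagg-2 and 0.108 in the other 6 libraries, and MD05G1005300 at 2.53 CPM in wt and 0.244 in the 6 knock-out libraries.

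The authors' deposited table, which compares each line with wt, lists 21 features at an adjusted p under 0.05 for mdagg-2 (12 higher, 9 lower), 480 for mdagg-3 (117 higher, 363 lower) and 110 for mdagg-4 (51 higher, 59 lower). DESeq2 run here on the 4 libraries of a line and wt called 20 of those 21, 477 of those 480 and all 110. Of the features in the authors' deposited table, 5 were higher in all 3 lines, with log2 fold changes of 1.95 to 3.81, and 1 was lower in all 3, MD05G1005300, with log2 fold changes of -3.52 to -3.21. In edgeR's test of the mean of the lines the 5 had log2 differences of 2.04 to 3.37 and adjusted p values of 0.36 to 0.788. No feature (0) was called higher, and 0 lower, in all 3 lines by edgeR, while DESeq2 on the 8 libraries gave 12 and 1.

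Because the 3 lines share the same wt libraries, the overlap of their calls was set beside that of unchanged groups. When counts without any group difference were simulated 8 times for the 8 libraries and each line was tested against wt with DESeq2 as above, 63.7 features per line passed the threshold on average, and 3.38 features were called in all 3 lines in the same direction (range 1 to 6). The authors' deposited table has 6 such features. The simulated lists held 59.3 to 72.3 calls per line and the authors' lists 21, 480 and 110, and since overlap grows with list length the simulated values are not like-for-like limits. Between mdagg-3 and mdagg-4, 18 higher calls of the authors' deposited table were shared, where independent lists would share 0.17 and the simulated unchanged groups shared 4 to 11. Of the lower calls they shared 7, where independent lists would share 0.66 and the simulation 2 to 5. Between mdagg-2 and mdagg-3 the table's calls shared 6 higher and 2 lower features, where the simulation gave 4 to 11 and 1 to 6, with 0.032 and 0.1 for independent lists. Between mdagg-2 and mdagg-4 they shared 7 higher and 7 lower features, where the simulation gave 5 to 9 and 0 to 4, with 0.017 and 0.016 for independent lists. The correlation of log2 differences across 27598 features was 0.7 between mdagg-2 and mdagg-3, 0.22 between mdagg-2 and mdagg-4 and 0.043 between mdagg-3 and mdagg-4, where simulated unchanged groups gave 0.5 for each pair. The covariances were 0.12, 0.037 and 0.007, and they differed from the simulated ones by 0.037, -0.051 and -0.08. With 2 wt libraries the controls could not be split into groups of 2, so part of any excess may come from the shared controls. The simulation drew each feature independently, so it held no shift common to many features or to same-numbered libraries. In the data the first component alone held 46.3% of the variance. Departures from the simulated overlaps, correlations and covariances, in either direction, therefore cannot be assigned to the lines.

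The lines were also compared with each other. MD17G1123100 was the single feature (1 of 32373) that differed between the 3 lines in edgeR's F test (F = 398, adjusted p = 0.000579), while 1027 features had an unadjusted p under 0.05 and DESeq2's likelihood ratio test called 67. It was at 19.7 ± 0.813 CPM in mdagg-2, 0.0908 ± 0.0104 in mdagg-3 and 0.12 ± 0.00588 in mdagg-4 (SD, n = 2 each). The features next to it in identifier order held 0 or 1 read in every library. The count of 1 was the same with each library left out in turn.

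Ordered by identifier, 2 runs of neighbouring features were shifted from wt, with most features of a run on the same side. The scan that found them was added after the data were examined. The first 275 of the 887 scanned features of field 14, with borders set on mdagg-2, had a median log2 difference of 0.36 from wt in mdagg-2 (95% interval 0.31 to 0.39), 0.39 in mdagg-3 (0.37 to 0.41) and 0.39 in mdagg-4 (0.36 to 0.41). These are ratios of 1.28, 1.31 and 1.31. In the mean of the lines 94.2% of the 275 features were higher than wt. Each of the 12 comparisons of 1 knock-out library with 1 wt library gave a positive median, from 0.32 to 0.41, while the wt libraries differed from each other by -0.04. The other 612 features of field 14 had medians of 0.02, -0.004 and 0.02 in the 3 lines. Scanned on their own, mdagg-3 and mdagg-4 gave runs of 326 and 332 features, with medians of 0.39 and 0.38. These runs began near the same identifier and ended beyond the 275 features. The other 612 features therefore include some that were raised in these lines. Features elsewhere matched on length and abundance had a median of -0.02. The median standard error was 0.252 for the mean of the lines. In simulated data with features drawn independently, unlike the real libraries, edgeR's test recovered 10% of 2-fold changes.

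In field 15, 51 consecutive features of 1658, from rank 685 to rank 735, were lower in mdagg-4 and not in the other lines. Their borders were set on replicate 1 of mdagg-4 and wt. In replicate 2 of both groups, which did not set the borders, the median log2 difference was -1.006 (95% interval -1.275 to -0.881), and 98% of the features were lower. Against the mean of both wt libraries the medians were -0.92 and -1.03 in the 2 mdagg-4 libraries, a ratio of 0.529 and 0.49, and between -0.04 and 0.08 in the 4 libraries of mdagg-2 and mdagg-3. One of these features, MD15G1165600, was at 21.2 ± 0.278 CPM in mdagg-4 (SD, n = 2) and 44.7 ± 3.77 in the other 6 libraries (SD, n = 6), with a log2 difference from wt of -0.98 ± 0.17 (SE, edgeR adjusted p = 0.556 and DESeq2 adjusted p = 0.00654, range over the alternatives 0.00654 to 1). Among the features that the authors' deposited table lists as lower in mdagg-4, 15 of 59 (25.4%) carry identifiers inside this run, which holds 106 of the 35596 features with an adjusted p (0.298%). The run was found in the same libraries, so this share describes the table and is no separate evidence. Of the features that the authors' deposited table lists as higher, 0 of 12 in mdagg-2, 7 of 117 in mdagg-3 (5.98%) and 1 of 51 in mdagg-4 (1.96%) lie in the field 14 run, which holds 1.41%, 1.42% and 1.42% of the features with an adjusted p.

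**Figure D3:**
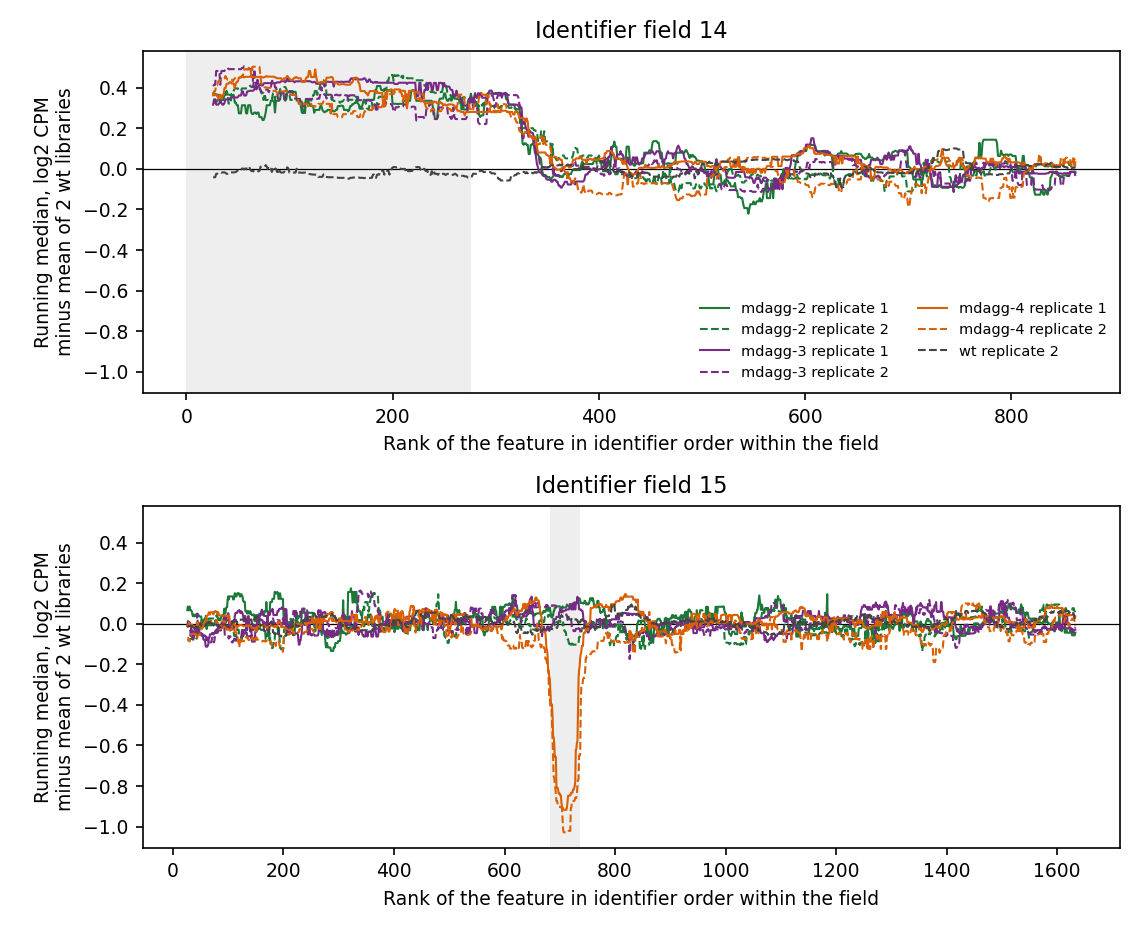
Running median over 51 features of log2 CPM minus the mean of the 2 wt libraries (y axis) against the rank of a feature in identifier order (x axis) for fields 14 and 15; lines are libraries (solid replicate 1, dashed replicate 2), wt replicate 1 mirrors wt replicate 2 and is left out, and grey marks the 275 and 51 features of the 2 runs. All 6 knock-out libraries lie above 0 over the field 14 run, and the 2 mdagg-4 libraries fall to about -1 in field 15.

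No other run with a median of at least 0.25 in either direction passed the scan's threshold in any of the 3 lines. The scan was not tried on inserted runs of smaller shift or shorter length, so such runs may have been missed. A run of 787 features in field 03 had a median of -0.05 in mdagg-2, and a run of 20 features in field 06 a median of -0.24 in mdagg-3. The medians of the whole fields other than field 14 lay within 0.044 of 0 in each line.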

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

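The F test between lines was set before the data were examined. The tests of the spread between features and of the length trend were chosen after their patterns but before their own results were seen, and the other tests of this part after the results were seen.

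MD17G1123100 differed between the lines in edgeR's F test (adjusted p = 0.000579), with 588 and 565 reads in the mdagg-2 libraries and 3 to 5 in each other library.

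The 51 features of field 15 also differed between lines. In the replicate 2 libraries alone, which did not set the borders, the median of mdagg-4 minus the mean of the other lines was -1.075. The same difference was taken in 16533 overlapping runs of 51 consecutive features elsewhere, each within 1 of the 18 fields. Their medians lay between -0.224 and 0.184. That places the run among features and is not a test over plants, and the run had been noticed in both mdagg-4 libraries before. A scaling or depth factor common to a library cancels in the median of the run minus that of the rest of its field. That difference was -0.964 in the replicate 2 libraries (95% interval -1.217 to -0.841). The run had been chosen for differing from other features after the median was subtracted, so this is no separate test of such a factor. Separate regulation of single features would spread their differences, yet the median absolute deviation was 1.01 times that of matched features elsewhere (0.139 and 0.138). That value used both mdagg-4 libraries, including replicate 1, which set the borders. A spread between features cannot speak to neighbouring features regulated together. The loss of 1 of 2 copies of a chromosome stretch, with transcript output in proportion, predicts -1, and the libraries that did not set the borders gave -1.006 (95% interval -1.275 to -0.881). Intervals over features do not measure the spread between plants, so they cannot decide between -1 and a nearby value. Replicate 1 of mdagg-4, which set the borders, gave -0.918 against the mean of wt. Its interval of -0.992 to -0.833 leaves out -1. Both libraries together gave -0.984 (-1.065 to -0.927). This is consistent with a deletion of 1 copy in mdagg-4, as a hypothesis from RNA alone, and DNA read depth over the run, which would test it, was not analysed here.

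The field 14 run was higher in all 6 knock-out libraries. A scaling or depth factor common to a library cancels in the median of the run minus that of the rest of its field. In the lines that did not set the borders this difference was 0.396 (mdagg-3, 95% interval 0.364 to 0.427) and 0.371 (mdagg-4, 0.337 to 0.409). It is no separate test of such a factor, because the run was chosen for differing from other features after the median was subtracted. Both lines also share the wt libraries that set the borders, and their own scans had given the run. Separate regulation of single features is argued against by a spread 1.08 times that of matched features. That spread used the mean of the lines, including mdagg-2, which set the borders, and cannot speak to neighbouring features regulated together. A gain of 1 copy on 2 in every cell, with output in proportion, predicts 0.585. The 95% interval over features of the median for the mean of the lines ended at 0.391. The highest median of the 12 single-library comparisons, which share 2 wt libraries, was 0.405. In these libraries this size of change is argued against, but the interval does not measure the spread between plants. A smaller gain, a gain in part of the cells, a damped response to a gain, or a loss in part of the cells of the wt plants, or a damped response to one, may still account for it and was not tested, for which DNA read depth would be needed. All 3 lines were compared with the same 2 wt libraries, so the design does not separate a state of the wt plants from a state shared by the lines.

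Libraries of 1 group stood as far apart as libraries of different groups. Removing each library's trend over feature length left 46.5% of the variance on the first component (46.3% before), which argues against a length bias. Depth stays open: the deeper library of a group scored higher on the first component in wt, mdagg-3 and mdagg-4, by 36.5, 2.74 and 77.7, and lower in mdagg-2, with a difference of -142. A shift shared by same-numbered libraries stays open: the correlations of their deviations over the 6 pairs of groups ranged from -0.31 to 0.53, while replicate 2 scored above replicate 1 on the first component, and had the larger TMM factor, in all 4 groups. The libraries at the ends of the component also had the lowest and highest TMM factors, 0.9125 in mdagg-2 replicate 1 and 1.114 in mdagg-4 replicate 2. A difference in the composition of the libraries was not tested and stays open. The pattern lies within groups, so no biological explanation was tested, and a difference in the state of the sampled leaves stays open.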

How the results depend on the processing

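The counts of features past the threshold were the same as reported with DESeq2 size factors and with the effective-length offset. Replicate numbers were taken not to pair the libraries, because the design text does not tie a number to the same experiment across groups. The correlations of deviations over the 6 pairs of groups, from -0.31 to 0.53, leave open whether they do. With the replicate block the counts were also the same: 0 higher and 0 lower for the mean of the lines, 1 higher in mdagg-2, 0 in mdagg-3, 1 higher in mdagg-4 and 1 between lines. Without the low-count filter the mean of the lines gave 2 higher and 4 lower, mdagg-4 gave 1 lower and the comparison between lines gave 4. With DESeq2 on 8 libraries the counts were 53 higher and 19 lower for the mean of the lines, 28 and 9 for mdagg-2, 31 and 9 for mdagg-3, 50 and 44 for mdagg-4, 12 and 1 in all 3 lines, and 67 between lines. That fit also used no low-count filter. With the 6 knock-out libraries as one group 1 feature was lower for the mean of the lines. With only the 4 libraries of a line and wt, edgeR called 0 features higher in mdagg-2 and 0 higher in mdagg-4, where the fit has 2 fewer residual degrees of freedom than the 4 of the fit of all libraries. Of the settings added after the data were examined, DESeq2 on those 4 libraries gave 12 higher and 8 lower for mdagg-2, 116 and 361 for mdagg-3, 52 and 60 for mdagg-4, and 4 and 1 in all 3 lines. In simulated unchanged groups, with 32373 filtered features drawn independently, that setting called 63.7 features per line. The fits of the deposited counts used no low-count filter and gave fewer calls in mdagg-2 and more in the other lines. The simulated number is therefore no measured rate of false calls for them. Limma-voom called 0 higher in mdagg-4. Without mdagg-2 replicate 1 and mdagg-4 replicate 2 together, 1 feature each was lower for the mean of the lines, in mdagg-3 and in mdagg-4. Leaving out the features of the 2 runs changed no count.

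With each library left out in turn, where the lone library of a group is assumed to vary like the other groups, counts ranged from 0 to 1 lower for the mean of the lines (1 without either mdagg-2 library), 0 to 1 higher in mdagg-2 (0 without wt replicate 2), 0 to 1 higher in mdagg-4 (0 without either wt, mdagg-3 or mdagg-4 library) and 0 to 1 lower in mdagg-4 (1 without either mdagg-2 library). The cause of these changes was not tested. MD13G1190500 in mdagg-4 lost its call in 8 of 18 alternatives, with log2 differences of 4.72 to 4.93, and MD17G1123100 in mdagg-2 in 2 of 18, with 7.04 to 7.91. MD05G1005300 gained one in 3 of 17 and MD15G1165600 in 1 of 17. None of these (0) changed direction. The median of the field 14 run stayed between 0.327 and 0.411 over 3 lines and their alternatives, and that of the field 15 run in mdagg-4 between -1.028 and -0.918. The tests of gene lists, and the estimated correlation planned for them, were not run because no identifier could be matched to a list. At these totals a feature at 3 reads stands at 0.0811 to 0.105 CPM, so features such as MD17G1123100 outside mdagg-2 lie near the limit of detection.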
